A study of Mus musculus with 9 samples.

How the data were processed

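RNA was sequenced from B16F10 cells, a mouse melanoma line, grown in DMEM with 10% FBS. The 9 libraries fell into 3 groups of 3 by their titles: GFPsg, a guide named for GFP with the genotype given as wild type, and Tada2bsg1 and Tada2bsg2, both with the genotype given as Tada2b knockout. Per the labels' protocols, RNA was extracted with the RNeasy Plus Mini kit and libraries were made with the KAPA Stranded mRNA-Seq kit. The titles name replicates 1 to 3 in each group, and nothing in the labels says whether these were separate cultures, so that every p-value measures only the spread between these samples, which may be technical.

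The deposited table holds raw counts of reads per gene, with 1 column per library and no normalization by the authors, as its values show. Per the submitters' processing notes, the tools used were bcl2fastq, HISAT2 and HTSeq with the mm10 build. Their versions, the annotation release, the strand setting and any read filter were not given in the sources used here. HTSeq by default drops reads that align to several places, so genes with near-identical copies can be counted low or unevenly, and without a stated strand setting reads from overlapping and antisense genes cannot be told apart. The values were whole numbers, and no row held a total or an unassigned class. Of 54752 Ensembl gene identifiers, 54723 matched GENCODE release M21, an annotation of mm10, which gave the symbols, gene types and coordinates used here, and 29 did not match. A further 22617 rows were 0 in every library.

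Library totals ranged from 70.6 to 76.9 M counts (M, mega). Replicate libraries were compared pairwise by a chi-square test of their counts, and the statistic per degree of freedom ran from 7.12 to 22.7, so that no pair was identical or agreed within sampling noise. The highest value was that of GFPsg replicates 1 and 2. The common biological coefficient of variation was 0.0526.

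Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group with a count minimum of 10, which kept 17931 genes holding 99.97% of counts. Libraries were scaled by trimmed mean of M-values (TMM), and the quasi-likelihood F test was applied to 1 fit of all 3 groups. It gave 4 contrasts. The knockout contrast set the mean of both guides against GFPsg, each guide was then set against GFPsg, and guide 2 was set against guide 1. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called, with no threshold on fold change. Fold changes are on the log2 scale. Their standard errors were derived here as the size of the change over the square root of its F statistic. CPM (counts scaled to a library of 1 M counts) were computed here from TMM-scaled library sizes and are given as mean ± SD over 3 libraries.

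A set of 34 gene lists, holding 1046 listed genes, was fixed before the data were examined. Those with at least 5 tested genes, 33 in number, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The alternatives were camera with an estimated correlation and fry. Camera asks whether a list shifted relative to all other genes, and fry whether it changed at all. The lists cover the SAGA and ATAC complexes, major histocompatibility complex (MHC) class I presentation, interferon response, interferon receptors and signalling, checkpoint and NK ligands, NF-kB and chemokines, death receptors and apoptosis, melanocyte pigmentation, the invasive and neural crest melanoma state, extracellular matrix, MAPK output, TGF-beta response, Myc targets with ribosome biogenesis, S phase, G2 and mitosis, p53 targets, oxidative phosphorylation, glycolysis, hypoxia, cholesterol biosynthesis, fatty acid synthesis, the integrated stress response, the unfolded protein response, lysosome and autophagy, antioxidants and ferroptosis, histone acetylation and chromatin, glycosylation and heparan sulfate, cytosolic ribosomal proteins, mitochondrial genome transcripts and immediate early genes. Markers of leukocytes, of fibroblasts and endothelium, and of epithelium served for other cell types.

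Genes to be named were chosen by a rule fixed with the lists. Tada2b came first. Next came the 10 genes with the highest and the 10 with the lowest change, ranked by the smaller of the changes seen with each guide, among genes called in the same direction with both guides, with a mean of at least 5 CPM and without a predicted or clone name. Up to 4 members of each list with the lowest p in the knockout contrast followed, then the 5 largest rises and 5 largest falls between the guides. Some genes picked by the rule are not reported here and are left out of the counts of named genes. A few list members outside that rule, and genes named because a count was 5 or fewer, were chosen after their values were seen.

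The pipeline was tested on counts simulated from the mean of the controls, the fitted dispersion of each gene and the real library sizes, with 50 genes changed at each of 4 fold sizes. Changed genes, also those of the list test, were drawn from genes with a mean of at least 1 CPM. Recovery of genes with lower counts was therefore not tested. In the knockout contrast, with 17227 genes run, 76% of genes changed 1.25-fold, 92% at 1.5-fold and 100% at 2-fold and 4-fold were recovered, with 15 false calls among 17027 unchanged genes. In the simulated contrast of guide 2 with guide 1, with 17245 genes run, recovery was 78% at 1.25-fold, 88% at 1.5-fold and 100% at the larger folds, with 17 false calls among 17045. In the list test, 1 shifted list of 30 genes was found and 0 of the 32 others was called by camera. Simulated genes were drawn independently, so this run could not show false list calls that come from correlation between genes. In the real libraries the estimated correlation was 0.58 for oxidative phosphorylation genes and 0.62 for cytosolic ribosomal protein genes. With few genes changed, the runs also did not test scaling where as many genes change as in the real data.

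Alternatives tried were DESeq2 size factors within edgeR, library size alone, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 50 reads in at least 3 libraries, a fold change of at least 2, the replicate number as a block, both guides pooled as 1 group, fits of only the 2 groups compared, and leaving out each library in turn. The restriction to protein-coding genes, and all list alternatives for guide 2 against guide 1, were chosen after seeing the data. Comparisons that share the control libraries were set beside 20 simulations of unchanged groups, in which both guides shared simulated controls. No library was left out of the main comparisons.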

Results

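Gene expression was profiled in B16F10 mouse melanoma cells to compare control cells with cells labelled as Tada2b knockout. Tada2b encodes an adaptor of the histone acetyltransferase module of SAGA, a coactivator complex that acetylates histone H3 and contacts transcription factors at promoters. The knockout label was represented by 2 guides, Tada2bsg1 (guide 1) and Tada2bsg2 (guide 2), with 3 libraries each, and the control by 3 libraries with a guide named for GFP (GFPsg). Total counts per library averaged 73.6 ± 2.60 M in GFPsg, 75.7 ± 1.93 M with guide 1 and 73.6 ± 2.71 M with guide 2 (M, mega; mean ± SD, n = 3). Depth was thus even between groups. On the first principal component, which held 68.1% of the variance, the controls lay between −67.3 and −66.6, the guide 1 libraries between 39.7 and 40.1 and the guide 2 libraries between 26.3 and 28.2.

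The targeted gene was examined first in every library. Tada2b (ENSMUSG00000029196) lies on chromosome 5 from 36473670 to 36484285 on the minus strand of mm10. It was counted at 28.0, 25.2 and 26.6 CPM in the GFPsg libraries (2070, 1679 and 1902 reads), at 32.3, 33.3 and 32.7 CPM with guide 1 (2548, 2479 and 2552 reads) and at 29.0, 26.0 and 25.9 CPM with guide 2 (2201, 2016 and 1856 reads). Its log2 change in the knockout contrast was 0.16 ± 0.05 (SE; edgeR adjusted p = 0.0101), a call that was lost without GFPsg replicate 2 (log2 change 0.14, adjusted p = 0.0534, with adjusted p from 0.00124 to 0.0534 over the 17 alternatives run for this gene). The fold-change threshold, the pooled guides and the fits of only the 2 groups compared were not among these. With guide 1 Tada2b rose by 0.30 (edgeR adjusted p = 0.000213), and with guide 2 the change was 0.02 (adjusted p = 0.806). With library size alone the change was 0.24 in the knockout contrast and 0.11 with guide 2, where the gene was still not called (adjusted p = 0.189, with 0.189 to 0.952 over the same alternatives). The mRNA was therefore not lower in the libraries labelled knockout. A frameshift need not lower the mRNA of a gene, and counts summed over the gene do not show the edited site, so these values do not check the label, and the libraries are called labelled knockout throughout.

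In the libraries labelled knockout, interferon-inducible genes and most MHC class I genes rose, while most pigmentation, cholesterol biosynthesis and unfolded protein response genes fell. Most genes of the extracellular matrix and of the invasive melanoma state also rose, but some members fell and neither list was called by camera with an estimated correlation (adjusted p = 0.102 for each). Col1a1, which encodes a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), went from 7.27 ± 0.13 CPM in GFPsg to 225 ± 5.57 CPM with guide 1 and 202 ± 16.1 CPM with guide 2 (mean ± SD, n = 3), 29.3-fold in the knockout contrast. Tyr, which encodes tyrosinase, the rate-limiting enzyme of melanin synthesis (ENSMUSG00000004651, chromosome 7, 87424771 to 87493512), went from 692 ± 38.9 CPM to 92.3 ± 1.10 and 146 ± 8.42 CPM.

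edgeR called 9141 of 17931 genes (51.0%) in the knockout contrast, 4426 higher and 4715 lower. Changes of at least 2-fold were made by 2010 of them, 1233 higher and 777 lower. The direction of small changes depended on scaling, since the share of called genes that were higher was 48.4% with TMM and 63.3% with library size alone, under which the median log2 change of all tested genes moved from −0.02 to 0.07.

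Ankrd1, a cardiac ankyrin repeat protein that is induced by mechanical stress (ENSMUSG00000024803, chromosome 19, 36111961 to 36120099), had the largest rise among the genes ranked by the smaller of the changes with each guide. It went from 0.16 ± 0.03 CPM in GFPsg to 25.5 ± 0.91 CPM with guide 1 and 18.2 ± 1.48 CPM with guide 2, a log2 change of 7.02 ± 0.12 (SE; edgeR adjusted p = 2.9e-17). Behind it came Apol9a (6.30 ± 0.18) and Apol9b (5.82 ± 0.12), adjacent apolipoprotein L genes induced by interferon, then Ifi204 (5.68 ± 0.11), Ifi205 (5.50 ± 0.15) and Ifi211 (5.44 ± 0.09), members of the p200 family of interferon-inducible genes. Apol9a and Apol9b are near-identical to each other and the p200 genes are similar within their family, so the split of reads among them is uncertain. Tpm2, a tropomyosin, rose by 4.90 ± 0.10, Col1a1 by 4.87 ± 0.06, the small heat shock gene Hspb7 by 4.71 ± 0.08 and the transglutaminase gene Tgm2 by 4.52 ± 0.13 on the log2 scale.

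Among the genes that fell and passed the limits of the naming rule, Mgll had the largest change by the same ranking. It encodes monoacylglycerol lipase (ENSMUSG00000033174, chromosome 6, 88724412 to 88828360), and it went from 45.8 ± 0.90 CPM in GFPsg to 3.08 ± 0.15 CPM with guide 1 and 5.91 ± 0.14 CPM with guide 2, a log2 change of −3.42 ± 0.05 (SE; edgeR adjusted p = 2.8e-18). The receptor gene Gpr37 fell by 3.01 on the log2 scale. Pigment cell genes lay close by. Oca2, a melanosomal transporter, fell by 2.91 ± 0.08, Trpm1, a channel gene that MITF activates, by 2.87 ± 0.03 (from 377 ± 6.79 CPM to 39.8 ± 0.63 and 66.7 ± 2.89 CPM) and Tyr by 2.58 ± 0.04. The nuclear receptor gene Nr4a3 fell by 2.63, the sodium channel gene Scn1a by 2.56, Ppp1r16b by 2.51 and Hpse, which encodes heparanase, by 2.42. All of these 9 had edgeR adjusted p-values of 7.4e-14 or below.

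**Figure D1:**
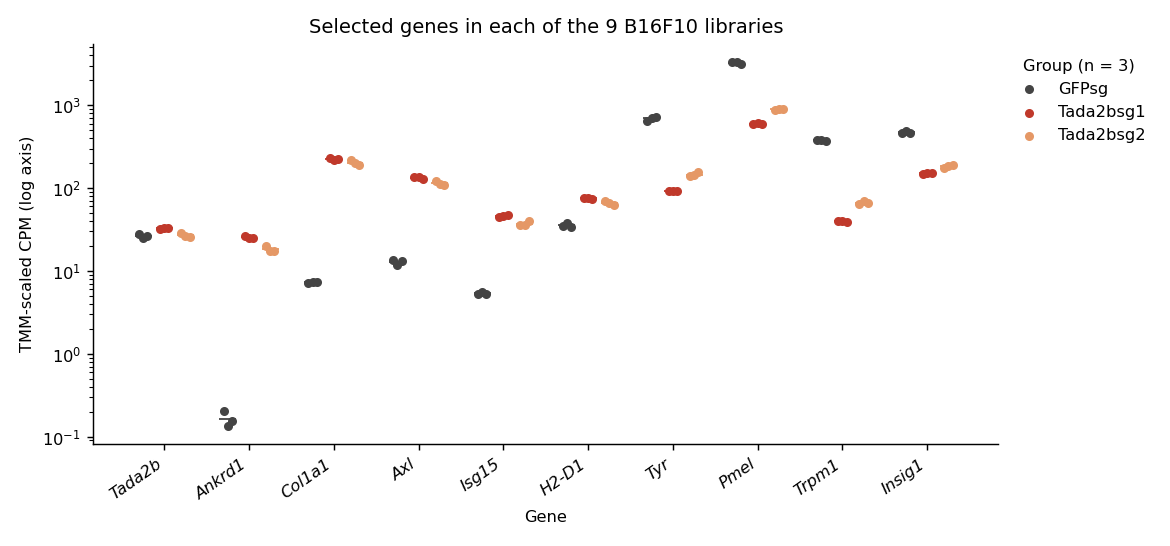
TMM-scaled CPM on a log axis of 10 genes in each of the 9 libraries, with GFPsg in grey, Tada2bsg1 in red and Tada2bsg2 in orange, where points are libraries and short lines are group means (n = 3). Tada2b lies between 25.2 and 33.3 CPM in all libraries, and the other genes separate the controls from both guides.

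Immune genes rose across several lists. In the interferon response list all 44 tested genes rose, with a median log2 change of 2.23 (camera adjusted p = 5.96e-30, and adjusted p = 0.0385 with an estimated correlation), and 44 were called when adjusted over the list alone. Usp18, which removes ISG15 from proteins, rose by 3.90 ± 0.07, Rtp4 by 3.45, the ubiquitin-like modifier gene Isg15 by 2.95 ± 0.06 (from 5.39 ± 0.18 CPM to 46.3 ± 1.55 and 37.2 ± 2.29 CPM), Irf9 by 2.77 and Ifitm3 by 1.93. In the MHC class I list 17 genes rose and 3 fell, with 20 called when adjusted over the list alone and a median of 1.18 (camera adjusted p = 1.74e-06, and adjusted p = 0.0150 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, rose by 2.56 ± 0.11, the peptide-loading gene Tapbp by 1.51, the trimming peptidase gene Erap1 by 1.17, B2m by 0.74 and the heavy chain gene H2-D1 by 0.98 (from 35.5 ± 1.68 CPM to 74.8 ± 0.52 and 65.9 ± 3.69 CPM). The H2 heavy chain genes are similar in sequence, so their single values are uncertain. The 3 that fell, Calr (−0.49), Pdia3 (−0.30) and Canx (−0.28), are general chaperones of the endoplasmic reticulum.

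Among interferon receptor and signalling genes 12 rose, 4 fell and 4 were not called, with 16 called when adjusted over the list alone, a median of 0.26 and a camera adjusted p of 0.00603 (adjusted p = 0.0724 with an estimated correlation). Irf1 rose by 1.49 and Stat3 by 1.39. Those that fell were the receptor genes Ifngr2 (−0.68) and Ifnar1 (−0.38), with Jak2 (−0.16) and Irf3 (−0.11). In the NF-kB and chemokine list 15 genes rose, Birc3 fell (−0.45) and 2 were not called, with 16 called when adjusted over the list alone and a median of 0.81 (camera adjusted p = 2.06e-07, and adjusted p = 0.0150 with an estimated correlation). Bcl3 rose by 3.78, Csf1, the macrophage growth factor, by 2.86 (from 8.77 ± 0.58 CPM to 67.1 ± 2.23 and 60.2 ± 3.63 CPM), Tnfaip2 by 1.15 and Nfkb1 by 1.06. Of the checkpoint and NK ligand genes 7 rose, Cd276 fell (−0.51) and 6 were not called, with 8 called when adjusted over the list alone, a median of 0.29 and a camera adjusted p of 0.0207 (adjusted p = 0.102 with an estimated correlation). Lgals9 rose by 1.75, Pvr by 1.04, the phagocytosis checkpoint gene Cd47 by 0.66 and Cd274, which encodes PD-L1, by 0.30.

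Pigment cell genes fell together. In the melanocyte pigmentation list 27 of 28 tested genes fell, with 28 called when adjusted over the list alone and a median of −1.75 (camera adjusted p = 1.46e-19, and adjusted p = 0.0150 with an estimated correlation). Pmel, the melanosome fibril gene, went from 3249 ± 91.1 CPM to 597 ± 3.63 and 900 ± 13.8 CPM, a log2 change of −2.15 ± 0.03, and the transporter gene Slc45a2 fell by 1.95. The lineage transcription factor genes Mitf (−1.46) and Sox10 (−1.16) fell, as did Dct (−1.87), Mlana (−1.90) and Tyrp1 (−1.59). Slc7a11, a cystine transporter gene that also stood in the antioxidant list, was the member that rose (0.94).

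Genes of the invasive and neural crest melanoma state and of the extracellular matrix rose. Of the former 13 rose, 3 fell and 1 was not called, with 16 called when adjusted over the list alone and a median of 1.44 (camera adjusted p = 8.71e-06, and adjusted p = 0.102 with an estimated correlation). The receptor kinase gene Axl, high in dedifferentiated melanoma, went from 12.7 ± 0.98 CPM to 133 ± 2.92 and 114 ± 6.23 CPM (3.27 ± 0.05), Ccn2 rose by 2.89 and Loxl2 by 2.54. Sox9 (−1.19), Zeb2 (−0.34) and Birc3 fell. Of the matrix genes 25 rose, 6 fell and 1 was not called, with 31 called when adjusted over the list alone and a median of 1.32 (camera adjusted p = 7.12e-08, and adjusted p = 0.102 with an estimated correlation). Besides Col1a1, Thbs1 rose by 4.04, Timp1 by 2.80, Ltbp1 by 3.03 and Fn1 by 2.37, while the basement membrane gene Nid1 (−1.17) and Fbln1 (−1.57) fell. In the TGF-beta list 12 genes rose, 6 fell and 3 were not called, with 19 called when adjusted over the list alone, a median of 0.54 and a camera adjusted p of 0.0302 (adjusted p = 0.188 with an estimated correlation). Ltbp1 and Ccn2 were in it too, and Id2, an inhibitor of differentiation, fell by 1.79.

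Markers of other cell types were measured beside these groups. Of 8 tested fibroblast and endothelial markers 5 rose, 1 fell and 2 were not called, with 6 called when adjusted over the list alone, a median of 1.39 and a camera adjusted p of 0.0146 (adjusted p = 0.102 with an estimated correlation). Col1a1 and Col1a2 (1.68) in that list are also matrix genes, Pdgfrb rose by 1.45 and the muscle filament gene Des by 1.33, and Vwf fell by 2.11. Col1a2 stood at 3.15 ± 0.42 CPM in GFPsg and at 10.97 ± 0.26 and 9.34 ± 0.12 CPM with the guides. Of 5 tested leukocyte markers, Cd68 (1.09) and Lyz2 (1.08) rose, each to a mean under 4 CPM, Cx3cr1 was called higher from 1 to 5 reads per control library, Fcer1g fell (−1.19) and 1 was not called, with a list median of 1.08 and no call (camera adjusted p = 0.222). Epithelial markers tested were 3 in number, too few for a list test. Cdh1, the E-cadherin gene, fell by 2.03, Krt7 rose by 1.37 and Grhl2 was not called (−0.23).

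Lipid synthesis genes fell. Of 26 cholesterol biosynthesis genes 25 fell and Ggps1 was not called, with 25 called when adjusted over the list alone and a median of −0.86 (camera adjusted p = 2.33e-14, and adjusted p = 0.0150 with an estimated correlation). Insig1, which holds the sterol sensor in the endoplasmic reticulum, went from 470 ± 12.6 CPM to 151 ± 1.98 and 183 ± 6.05 CPM (−1.50 ± 0.03), Msmo1 fell by 1.22, Cyp51 by 1.11 and Hmgcs1 by 1.05. In the fatty acid list 14 genes fell, 5 rose and 4 were not called, with 20 called when adjusted over the list alone, a median of −0.32 and a camera adjusted p of 0.00413 (adjusted p = 0.111 with an estimated correlation). Elovl6 fell by 0.96, Acly, which makes cytosolic acetyl-CoA, by 0.87 and Scd2 by 0.80, while Acsl1 rose by 0.88.

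Stress and organelle genes also shifted. In the unfolded protein response list 23 genes fell, Atf6 (0.31) and Sec24d (0.17) rose and 1 was not called, with 25 called when adjusted over the list alone and a median of −0.43 (camera adjusted p = 5.65e-08, and adjusted p = 0.0150 with an estimated correlation). Sdf2l1 fell by 1.00, Herpud1 by 0.82, Pdia4 by 0.73 and Dnajc3 by 0.70. The integrated stress response list had 22 genes lower, 8 higher and 8 not called, with 30 called when adjusted over the list alone, a median of −0.15 and a camera adjusted p of 0.0374 (adjusted p = 0.188 with an estimated correlation). Ddit3, which encodes CHOP, fell by 1.29 and Atf4 by 0.39, whereas Slc7a11 (0.94) and Nupr1 (0.84) rose. Among lysosome and autophagy genes 22 fell, 8 rose and 7 were not called, with 30 called when adjusted over the list alone, a median of −0.26 and a camera adjusted p of 0.00306 (adjusted p = 0.102 with an estimated correlation). Gpnmb, which was also in the pigmentation list, fell by 1.12, Ctsd by 0.71, Naglu by 0.66 and Hexa by 0.47. The antioxidant list had 16 genes higher, 8 lower and 6 not called, with 24 called when adjusted over the list alone, a median of 0.11 and a camera adjusted p of 0.0207 (adjusted p = 0.276 with an estimated correlation). The quinone reductase gene Nqo1 went from 20.6 ± 0.46 CPM to 106 ± 2.46 and 83.3 ± 0.80 CPM (2.19), the iron exporter gene Slc40a1 rose by 1.68 and Srxn1 by 1.48.

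Energy metabolism and ribosomal protein lists were called down by camera with the preset correlation, and none of them with an estimated correlation. Of 74 oxidative phosphorylation genes 50 fell and 24 were not called, with 55 called when adjusted over the list alone and a median of −0.18, or −0.09 with library size alone (camera adjusted p = 7.82e-06, and adjusted p = 0.491 with an estimated correlation). Sdhb and Ndufs8 each fell by 0.46. All 15 mitochondrial genome transcripts fell, with 15 called when adjusted over the list alone, a median of −0.40 and a camera adjusted p of 0.00148 (adjusted p = 0.398 with an estimated correlation). mt-Co1 fell by 0.54 and mt-Co3 by 0.50. The share of all counts on the mitochondrial chromosome was 1.83 ± 0.26% in GFPsg, where replicate 2 stood at 1.53%, against 1.38 ± 0.05% and 1.49 ± 0.06% with the guides. In the glycolysis list 15 genes fell, 5 rose and 5 were not called, with 20 called when adjusted over the list alone, a median of −0.19 and a camera adjusted p of 0.0166 (adjusted p = 0.302 with an estimated correlation). Aldoc fell by 1.14, Ldhb by 0.85, Aldoa (ENSMUSG00000030695) by 0.62 and Gpi1 by 0.53. In the hypoxia list 14 genes fell, 5 rose and 7 were not called, with 21 called when adjusted over the list alone, a median of −0.22 and a camera adjusted p of 0.0302 (adjusted p = 0.102 with an estimated correlation). Its most changed members rose, with Adm at 1.95, Egln3 at 1.52 and P4ha2 at 0.73, while Ak4 fell by 0.68. Of 77 cytosolic ribosomal protein genes 44 fell and 33 were not called, with 45 called when adjusted over the list alone, a median of −0.13 (−0.05 with library size alone) and a camera adjusted p of 2.37e-05 (adjusted p = 0.514 with an estimated correlation). Rplp0 fell by 0.35 and Rps15 by 0.25.

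Genes of the complex to which Tada2b belongs were tested as a list. In the SAGA list 14 of 24 genes rose, Tada1 fell (−0.15) and 9 were not called, with 15 called when adjusted over the list alone, a median of 0.14 and a camera adjusted p of 0.000830 (adjusted p = 0.0377 with an estimated correlation). Tada2b was one of its members. Taf9b went from 19.1 ± 1.24 CPM to 45.0 ± 0.97 and 41.8 ± 1.35 CPM, a log2 change of 1.18 ± 0.05, and the module scaffolds Supt20 (0.47), Tada3 (0.46) and Taf5l (0.30) rose. In the list of ATAC, a sister complex that uses Tada2a and shares Tada3 and the acetyltransferases, 3 of 13 genes rose, 5 fell and 5 were not called, with no call and a median of −0.05 that was 0.03 with library size alone (camera adjusted p = 0.534). Kat14 fell by 0.27, Yeats2 by 0.25 and Tada2a by 0.17, and the shared Kat2b rose by 0.23. In the list of other chromatin regulators 13 genes rose, 15 fell and 16 were not called, with no call and a median of −0.004 that was 0.08 with library size alone and 0.009 with DESeq2 size factors (camera adjusted p = 0.895). Hdac7 rose by 1.73 and Hdac5 by 0.47, and Hdac11 fell by 1.15 and Tet1 by 0.55.

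Growth-related and immediate early genes were tested next. Of 49 Myc targets and ribosome biogenesis genes 26 rose, 7 fell and 16 were not called, with 35 called when adjusted over the list alone, a median of 0.12 and a camera adjusted p of 0.00411 (adjusted p = 0.188 with an estimated correlation). Rrp12 rose by 0.61, Odc1 by 0.55 and Mybbp1a by 0.41, while Myc itself fell by 0.74. Immediate early genes had 12 members higher, 6 lower and 7 not called, with 18 called when adjusted over the list alone, a median of 0.59 and a camera adjusted p of 0.00882 (adjusted p = 0.188 with an estimated correlation). Ccn1 rose by 1.97 and Btg2 by 0.85, and Nr4a3, was the member with the largest fall (−2.63). The S phase list had 8 genes higher, 16 lower and 22 not called (median −0.04, or 0.05 with library size alone, camera adjusted p = 0.294), with Ccne1 at 0.38, Ccne2 at 0.37 and Pcna at −0.34. The G2 and mitosis list had 21 higher, 11 lower and 16 not called (median 0.05, or 0.14 with library size alone, camera adjusted p = 0.273), with Kif20a at 0.40, Hmmr at 0.32, Psrc1 at −0.66 and Cdc25b at −0.52.

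No call was made for 4 further lists, whose members went both ways. Among p53 targets 11 rose, 14 fell and 7 were not called (camera adjusted p = 0.425), and the median of −0.12 and the mean of 0.08 differed in sign. Plk2 rose by 1.58, and Trp53inp1 fell by 1.40 and Zmat3 by 0.89. Among genes of MAPK output 5 rose, 10 fell and 4 were not called (camera adjusted p = 0.139), with a median of −0.20 and a mean of 0.23. The receptor gene Epha2 rose by 3.67 and the phosphatase gene Dusp5 by 2.92, while Dusp4 fell by 1.31 and Phlda1 by 1.11. Among death receptor and apoptosis genes 11 rose, 9 fell and 8 were not called (median 0.02, camera adjusted p = 0.449), with Bcl2l11 at 0.94, Bid at 0.64, Tnfrsf1a at 0.53 and Apaf1 at −0.52. Among glycosylation and heparan sulfate genes 10 rose, 12 fell and 3 were not called (median −0.06, or 0.02 with library size alone, camera adjusted p = 0.509). The sialyltransferase genes St6gal1 and St3gal1 fell by 1.80 and 1.56 and the branching enzyme gene Mgat5 by 1.48, and Ext1 rose by 0.77.

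In all, camera called 24 of 33 lists in the knockout contrast, 13 up and 11 down, and 7 of them were called with an estimated correlation, namely those of the interferon response, MHC class I, NF-kB, pigmentation, cholesterol, the unfolded protein response and SAGA. With library size alone the calls of the TGF-beta list (camera adjusted p = 0.129, with 0.0255 to 0.188 over its camera alternatives) and of the integrated stress response list (adjusted p = 0.0802, with 0.0301 to 0.188) were lost, and the G2 and mitosis list was called up (adjusted p = 0.0467, with 0.0467 to 0.514).

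**Figure D2:**
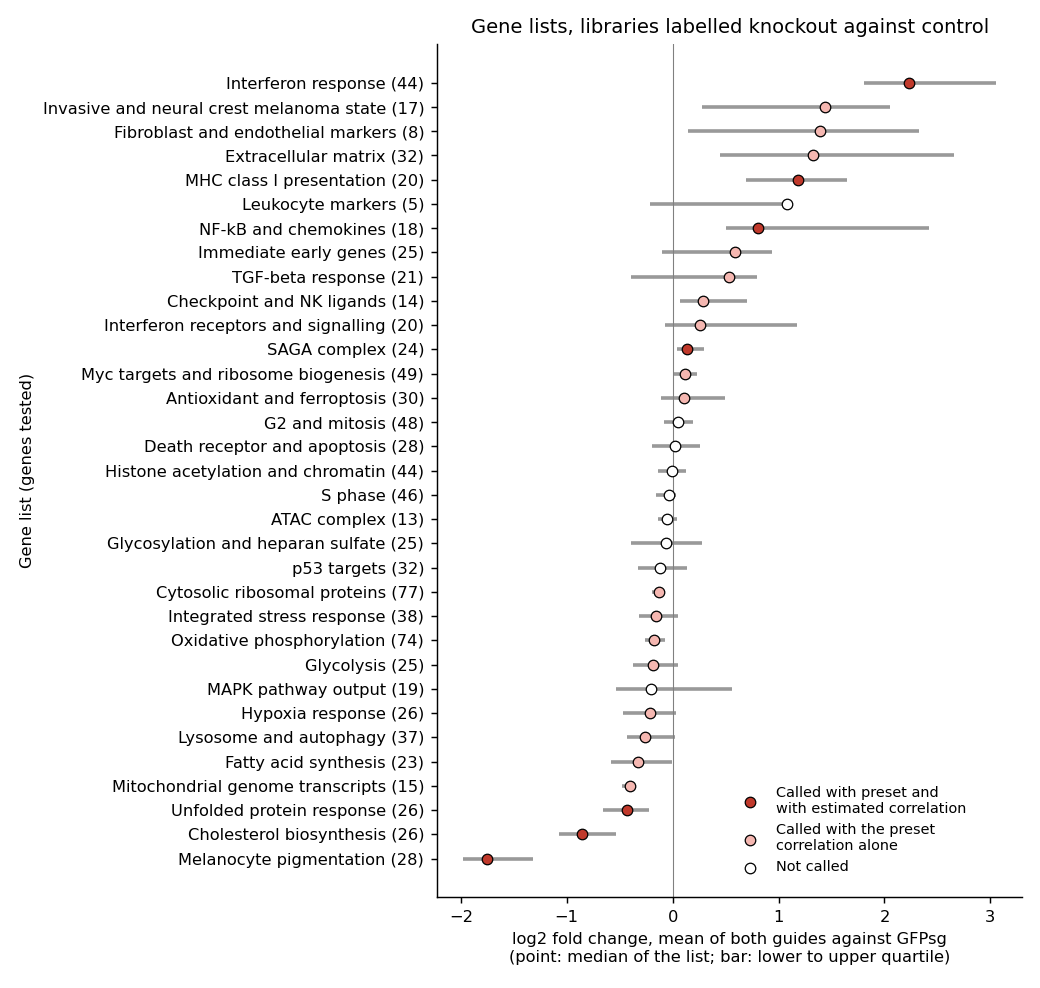
Median log2 change (points) and lower to upper quartile (bars) of the members of 33 gene lists in the libraries labelled knockout against GFPsg, with the number of tested genes in parentheses and colour for the 7 lists called by camera with both correlations, those called with the preset correlation alone and those not called. The medians run from −1.75 for pigmentation to 2.23 for the interferon response, and those of the ATAC, S phase, chromatin and glycosylation lists, none of them called, change sign with library size alone.

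Each guide was then compared with GFPsg by itself. With guide 1, Ankrd1 rose by 7.26 ± 0.12 and Col1a1 by 4.95 ± 0.06, and Mgll fell by 3.89 ± 0.06, Trpm1 by 3.24 ± 0.04 and Tyr by 2.91 ± 0.05 on the log2 scale (SE). The interferon response list had 43 of 44 genes higher, with Ifit2 not called, at a median of 2.29 (camera adjusted p = 4.32e-30, and adjusted p = 0.0381 with an estimated correlation). In the pigmentation list 27 of 28 fell, at a median of −1.93 (camera adjusted p = 8.27e-21, and adjusted p = 0.0146 with an estimated correlation). edgeR called 8677 genes, 4276 higher and 4401 lower, of which 2157 changed at least 2-fold. The share higher was 49.3% with TMM and 63.1% with library size alone. Camera called 23 lists, 13 up and 10 down, those called in the knockout contrast except the integrated stress response, and 7 were called with an estimated correlation. With library size alone the calls of the ribosomal protein list (camera adjusted p = 0.0618, with 4.87e-05 to 0.597 over its camera alternatives) and of the TGF-beta list (adjusted p = 0.130, with 0.0214 to 0.194) were lost for this guide, and the MAPK list was called down and the G2 and mitosis list up (adjusted p = 0.0467, with 0.0467 to 0.5002, for each).

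With guide 2, Ankrd1 rose by 6.77 ± 0.13 and Col1a1 by 4.79 ± 0.06, and the log2 changes of Mgll, Trpm1 and Tyr were −2.96 ± 0.06, −2.50 ± 0.04 and −2.25 ± 0.05 (SE). All 44 interferon response genes rose, at a median of 2.17 (camera adjusted p = 8.75e-33, and adjusted p = 0.0365 with an estimated correlation), and 27 of 28 pigmentation genes fell, at a median of −1.58 (camera adjusted p = 2.10e-20, and adjusted p = 0.0141 with an estimated correlation). edgeR called 8092 genes, 3963 higher and 4129 lower, of which 1757 changed at least 2-fold. The share higher was 49.0% with TMM and 65.1% with library size alone. Camera called 24 lists, 13 up and 11 down, and 7 were called with an estimated correlation. With library size alone the calls of the TGF-beta list (camera adjusted p = 0.106, with 0.0242 to 0.165 over its camera alternatives), of the checkpoint list (adjusted p = 0.0644, with 0.0314 to 0.130) and of the integrated stress response list (adjusted p = 0.0528, with 0.0186 to 0.164) were lost for this guide.

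The guides were next compared for overlap, since an effect of the targeted gene should appear with both. The interferon, matrix, pigmentation and cholesterol lists each had medians of the same sign with both guides. Both guides called 7065 genes in the same direction, 3519 higher and 3546 lower, and 1623 of these changed at least 2-fold with each guide. One gene, Gas7, was called in opposite directions, at −0.13 with guide 1 and 0.24 with guide 2. A further 1611 genes were called with guide 1 alone and 1026 with guide 2 alone. Independent lists of these sizes would share 1958 genes, 945 higher and 1013 lower. Across genes, which are not independent replicates, the log2 changes with the guides had a Pearson correlation of 0.949, and 86.0% of tested genes had the same sign. Simulations of unchanged groups set both guides against a shared set of 3 simulated controls. In them the mean correlation was 0.51, the same-sign share 66.8% and the highest number of genes called with both guides 1. They drew genes independently, so shifts common to many genes of a library were absent. The observed covariance was 0.661 against a simulated 0.0231, a difference of 0.638. With only 3 control libraries these could not be split between the guides. The share of jointly called genes that were higher was 49.8% with TMM and 65.4% with library size alone.

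**Figure D3:**
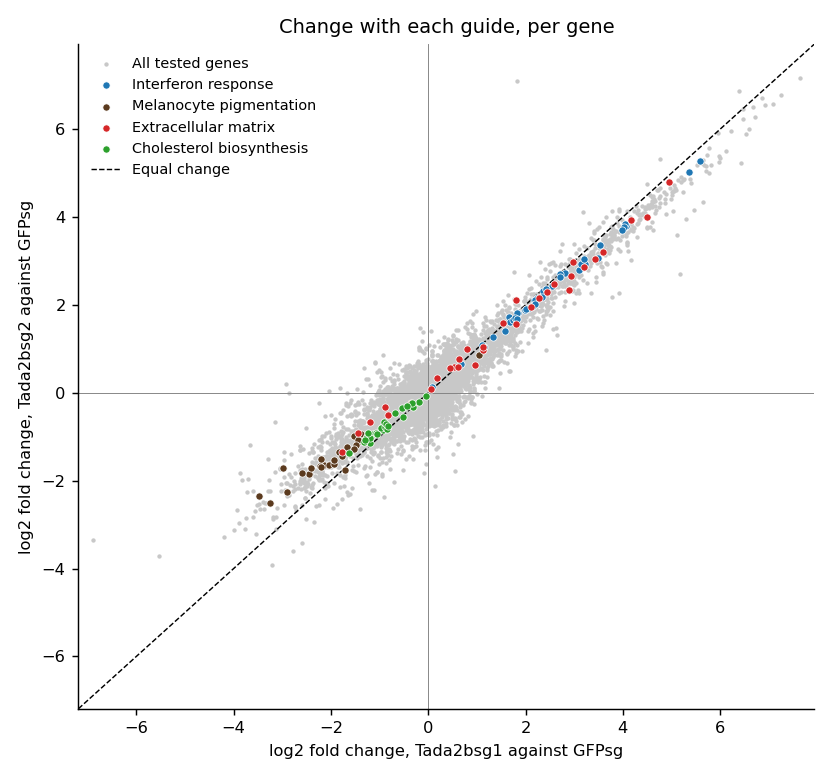
Log2 change of each tested gene with guide 1 (horizontal axis) and guide 2 (vertical axis) against GFPsg, with members of 4 gene lists in colour and a dashed line for equal change. Across genes the correlation is 0.949, and pigmentation genes have a median of −1.93 with guide 1 and −1.58 with guide 2.

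Guide 2 was finally compared with guide 1 directly. Pigmentation genes were higher with guide 2, that is, closer to the controls, and several interferon-inducible genes were lower. Among named genes, Oca2 was higher with guide 2 by 1.11 ± 0.11 on the log2 scale, the lipid transporter gene Abca12 by 1.03 ± 0.06, Gpr158 by 1.02 ± 0.10, Mgll by 0.94 ± 0.07 and Adam12 by 0.91 ± 0.11 (SE; edgeR adjusted p of 6.62e-05 or below). All 5 fell against GFPsg with each guide. Ifi204 was lower with guide 2 by −0.66 ± 0.07, Ifi205 by −0.64 ± 0.09, Apol9b by −0.61 ± 0.08 and Apol9a by −0.58 ± 0.11 (edgeR adjusted p of 0.00478 or below). All 4 rose with each guide, and the DESeq2 Wald test did not call the difference of Apol9a between the guides. CT010467.1, a locus at 39846353 on chromosome 17, stood at 475 ± 65.7, 522 ± 146 and 331 ± 73.9 CPM in the 3 groups and differed by −0.66 ± 0.17 (edgeR adjusted p = 0.0355). It is annotated as ribosomal RNA, and its call ended without guide 1 replicate 1 (adjusted p = 0.0581), guide 1 replicate 3 (0.226) or guide 2 replicate 2 (0.155). Tada2b was itself lower with guide 2 by −0.28 ± 0.05 (edgeR adjusted p = 0.00671).

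edgeR called 660 genes between the guides, 477 higher and 183 lower with guide 2, and 19 differed at least 2-fold, 15 higher and 4 lower. Of the 660, 620 had a smaller change from GFPsg with guide 2, 4 had a larger one (Coro2b, Fzd4, Katnal1 and Rps27rt), and 36 were not called in the knockout contrast. Over all 7065 genes called with both guides, 4986 (70.6%) had the smaller change with guide 2. The 4 genes, like the other genes here that fall outside the rule, were named after their values were seen. Camera called 14 lists, 7 up and 7 down. In the pigmentation list 24 genes were higher with guide 2, 1 was lower and 3 were not called, with 27 called when adjusted over the list alone and a median difference of 0.45 (camera adjusted p = 2.53e-34, and adjusted p = 0.00974 with an estimated correlation). In the cholesterol list 10 were higher and 16 not called, with 15 called when adjusted over the list alone and a median difference of 0.15 (camera adjusted p = 1.09e-09, and adjusted p = 0.0966 with an estimated correlation). In the interferon response list 4 were lower and 40 not called, with 10 called when adjusted over the list alone and a median difference of −0.11 (camera adjusted p = 6.01e-08, and adjusted p = 0.333 with an estimated correlation). The pigmentation list was the only list called with an estimated correlation. The count of 660 was 345 without guide 1 replicate 2, 335 without guide 1 replicate 3 and 399 without guide 2 replicate 2, and 1070 with no filter on low counts.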

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

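The contrast of guide 2 with guide 1 was planned, whereas the tests below of unedited cells, of scaling, of fibroblasts and of fewer melanocytic cells were chosen only after the result was seen. Groups held 3 libraries, too few for a test of single outlying libraries.

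The guides gave effects of different size against the same controls, by a direct edgeR test of the difference. It called 660 genes, and of the 141 genes named by the rule 61 differed, 60 with a smaller change with guide 2 and 1, CT010467.1, without a called change in the knockout contrast. Of these 61 genes, 10 had been picked by the rule for their difference between the guides. Values are log2 differences, guide 2 minus guide 1.

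Several pigment cell and other named genes that fell were less reduced with guide 2. The differences were 1.11 for Oca2, 0.74 for Trpm1, 0.66 for Tyr, 0.59 for Pmel, 0.57 for Slc45a2 and 0.28 for Gpnmb. Among the other genes with large falls they were 1.03 for Abca12, 1.02 for Gpr158, 0.94 for Mgll, 0.91 for Adam12, 0.80 for Nr4a3, 0.73 for Gpr37, 0.64 for Scn1a, 0.56 for Ppp1r16b and 0.50 for Hpse. Glycosylation genes differed by 0.61 (St3gal1), 0.49 (Mgat5) and 0.36 (St6gal1), and Id2 by 0.51, Tet1 by 0.45, Trp53inp1 by 0.37, Myc by 0.32, Dusp4 by 0.31, Zmat3 by 0.30, Phlda1 by 0.28, Psrc1 by 0.22 and Apaf1 by 0.20. Lipid genes differed by 0.27 (Insig1), 0.25 (Acly), 0.22 (Scd2), 0.21 (Msmo1), 0.19 (Cyp51), 0.19 (Hmgcs1) and 0.15 (Elovl6), and Naglu by 0.16, Gpi1 by 0.15 and Aldoa by 0.14.

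Some named genes that rose were less raised with guide 2. Interferon-inducible genes differed by −0.66 (Ifi204), −0.64 (Ifi205), −0.61 (Apol9b), −0.58 (Apol9a), −0.55 (Ifi211), −0.32 (Isg15), −0.24 (Usp18) and −0.18 (H2-D1). Apol9a was not called by the DESeq2 Wald test (adjusted p = 0.446). Matrix, contractile and invasive state genes differed by −0.49 (Ankrd1), −0.34 (Ltbp1), −0.32 (Tpm2), −0.28 (Ccn2), −0.27 (Timp1), −0.27 (Hspb7), −0.24 (Thbs1), −0.22 (Axl) and −0.21 (Ccn1). The rest were Nupr1 (−0.42), Nqo1 (−0.35), Plk2 (−0.26), Slc7a11 (−0.19) and Srxn1 (−0.14). Tada2b differed by −0.28, and CT010467.1, a ribosomal RNA locus, by −0.66.

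Camera called 14 lists between the guides. Their median differences were 0.45 for pigmentation, 0.15 for cholesterol, 0.13 for MAPK output, 0.12 for fatty acids, 0.0657 for the unfolded protein response, 0.0700 for chromatin regulators and 0.0343 for glycolysis, and −0.11 for the interferon response, −0.12 for MHC class I, −0.14 for NF-kB, −0.0764 for ribosomal proteins, −0.0645 for oxidative phosphorylation, −0.0348 for antioxidants and −0.51 for 5 leukocyte markers. With an estimated correlation only the pigmentation list was called (adjusted p = 0.00974, with 5.63e-36 to 0.00974 over its camera alternatives).

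The smaller changes with guide 2 had several possible technical sources. A scaling error between the guides would add the same amount to every gene. The median difference was instead 0.12 higher in genes that fell than in genes that rose, which argues against scaling as the sole source. Its 95% interval, 0.109 to 0.123, came from resampling genes, so it leaves out the spread between libraries. That test replaced one that asked for a median below −0.05 in genes that rose and was narrowly missed at −0.047. Unedited cells in the guide 2 cultures would add 1 share of control RNA to every gene. A scaling offset of 1% brought rising and falling genes closest. At that offset the implied share was 15.9% in genes that rose over 4-fold and 10.0% in genes that rose 2-fold to 4-fold. For the same classes of genes that fell it was 8.68% and 13.9%. The difference among genes that rose was 5.85 points (95% interval 4.51 to 8.38, from resampling genes). The median shares thus differed between classes, but that interval takes genes as independent and leaves out the spread between libraries. Whether unedited cells were the sole cause therefore stays open.

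That test of unedited cells also replaced an earlier one, in which genes changed over 4-fold gave shares of 16.9% for those that rose and 8.37% for those that fell. The earlier test was set aside because, over all genes changed at least 2-fold, the gap between rising and falling genes was 2.11 points and turned to −1.36 with a scaling offset of 2%. A mixture together with another cause, such as a weaker effect of the edit made by guide 2, may remain, and no test here separates these. The difference of 5.85 points bears only on a single uniform share and, without the spread between libraries, does not exclude it.

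Interferon response genes were higher in the libraries labelled knockout without any immune cell being part of the design. Leukocytes would bring their own abundant transcripts, yet the sum of 8 leukocyte genes reached at most 0.591 CPM in a library labelled knockout, against 0.870 to 1.09 CPM in the controls. Fcer1g, which fell, was part of this sum, whereas Cd68, Lyz2 and Cx3cr1, which were called higher, were not. Scaling does not account for the rise of the interferon response genes, since their list median was at least 2.24 with library size alone and with DESeq2 size factors. Interferon made by the cells cannot be told apart from a direct effect of the edit. The summed interferon transcripts, 9 to 31 reads per library, lay above every control in only 1 of 6 libraries labelled knockout. That rests on GFPsg replicate 2 (0.300 CPM). The other controls (0.162 and 0.126 CPM) lay below all 6 libraries labelled knockout (0.223 to 0.408 CPM). Ifnb1 alone had 1, 0 and 0 reads in the controls and 2, 8, 4, 15, 1 and 11 in the libraries labelled knockout. These reads are too few to decide. A response of the cells to the edit remains a hypothesis, and it could not be set against a cut elsewhere in the genome, since no control library with such a cut was analysed here.

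Pigmentation genes fell while matrix genes rose, which a mixture of cell types could give. Fibroblasts express Col1a2, Col3a1, Dcn and Lum along with Col1a1, but in the libraries labelled knockout the highest of these was at 4.98% of Col1a1, which argues against fibroblasts. A lower share of pigmented cells would lower the melanosome genes alike if the other cells lacked these transcripts. The log2 changes of Tyrp1, Dct, Pmel, Mlana and Tyr instead spanned 0.98 (SE 0.05, from the highest and lowest gene alone), from −1.59 to −2.58. This argues against such a mixture as the sole cause. Other cells that express these genes in unequal parts could give unequal falls, which the test cannot address. A shift of the melanoma cells from a pigmented to an invasive state is a candidate explanation that stays a hypothesis, since it was found and tested on the same data.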

How the results depend on the processing

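Restriction to protein-coding genes, and the list alternatives for guide 2 against guide 1, were chosen after seeing the data, and the other settings were planned. Apart from Tada2b, given below, there were 150 results for named genes, of which 149 were called. Of these, 147 stayed called in the same direction in every setting run for single genes. The fold-change threshold, the pooled guides and the fits of only the 2 groups compared were not run for them. The rule had picked these genes for large changes or low p in the same data, so this count says little about other genes. The exceptions were CT010467.1 and Apol9a in the contrast of the guides. Of 132 results for lists 85 were called, and 70 stayed called in every setting of camera with the preset correlation.

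A fold change of at least 2 lowered the number of genes by construction, to 2010 in the knockout contrast, 2157 with guide 1, 1757 with guide 2, 1623 with both and 19 between the guides. No filter on low counts gave 1070 genes between the guides, of which 644 were among the 660, and the cause was not tested. The DESeq2 Wald test gave 980. An estimated correlation lowered the lists called to 7 in the knockout contrast, 7 with guide 1, 7 with guide 2 and 1 between the guides. Fry called 30 lists in each contrast with GFPsg and 13 between the guides. It called the p53 targets down with guide 1 (fry adjusted p = 0.0306) and up with guide 2 (fry adjusted p = 0.00311). Camera called them with neither guide and leaned down with guide 2 (adjusted p from 0.482 to 0.666 over the camera alternatives). The mean and median of these genes differ in sign. With library size alone the S phase list was called lower with guide 2 than with guide 1 (camera adjusted p = 0.0338, with 0.0304 to 0.375 over its camera alternatives).

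Leaving out 1 library at a time gave 8184 to 9225 genes in the knockout contrast, 7800 to 9045 with guide 1, 7176 to 8019 with guide 2, 6365 to 6979 with both and 335 to 808 between the guides. The last was 335 without Tada2bsg1 replicate 3, 345 without Tada2bsg1 replicate 2 and 399 without Tada2bsg2 replicate 2. For Tada2b the log2 change ran from 0.135 (without GFPsg replicate 2, adjusted p = 0.0534) to 0.198 in the knockout contrast and from −0.0196 to 0.0601 with guide 2. None of the 17 alternatives run for this gene called it with guide 2.

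With the replicate number as a block (replicate block) the counts were 9938, 9512 and 9023 for the knockout contrast, guide 1 and guide 2, 7807 for both and 1705 between the guides (979 higher and 726 lower with guide 2, all 660 among them). Libraries with the same number had residual correlations of −0.0121 to 0.1004, against −0.0884 to 0.0407 for other numbers, with 1 of 9 over 0.1. On average 9 of 9 libraries correlated best with those of their own number, a hint of a shared effect that comes from the data and not from the design. Since nothing in the labels pairs the libraries, the block was not used elsewhere.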

Other observations

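The gene lists in the next paragraph were chosen only after the results were seen, whereas the tests of chromosome 5 and of other splits of the libraries were planned.

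Genes of the cytoskeleton and of innate sensing had stood out among single genes, and 4 more lists were drawn up around them. Because genes already seen to change prompted these lists, their values are given without p-values. Contractile genes and targets of SRF, a transcription factor that responds to actin, rose in 17 of 25 cases and fell in 2, with a median log2 change of 0.83. Targets of YAP and TEAD, to which Ankrd1, Ccn1 and Ccn2 belong, rose in 14 of 20 cases and fell in 3, with a median of 0.74. All 6 tested genes of the p200 family rose, with a median of 5.47, and between the guides the family differed by −0.61, although the split of reads among these similar genes is uncertain. Genes of cytosolic nucleic acid sensing rose in 9 of 12 cases and fell in 1, with a median of 1.05. Cd74, the gene of the invariant chain that binds MHC class II proteins, was called higher (1.59).

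A cut at Tada2b could have removed the chromosome arm beyond it. Tested genes of chromosome 5 beyond Tada2b (935) had a median log2 change that differed by −0.0345 from that of the 270 before it. The 95% interval, −0.0871 to 0.00837, leaves out the bound of −0.1 set for such a loss. Intervals here came from resampling genes and do not include the spread between libraries. With guide 2 alone the difference was −0.0735 (95% interval −0.116 to −0.0286), which does not leave the bound out, so a loss in part of the guide 2 cells stays open.

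Other splits of the 9 libraries were tried for each count. In 100 splits drawn from 840, only the real split (1 of 100) reached the counts seen. These were 9141 genes in the knockout contrast, 7065 genes with both guides and 24 lists, against highest other values of 4861, 0 and 22. The split with 4861 genes had the 3 true controls as another of its groups. Splits that mix the groups carry the real effect into their spread, which lowers their counts. Libraries of a group that shared a culture would also rank the real split first, so the splits do not exclude chance. For single pairs of groups the 10 splits are too few for a share under 0.05. The real value was reached by 1 split of 10 in each case, with 8677, 8092 and 660 genes for guide 1, guide 2 and guide 2 against guide 1 and a highest other value of 0 genes in each, and with 23, 24 and 14 lists against highest other values of 12, 13 and 8.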
